A study of Mus musculus with 4 samples.

How the data were processed

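RNA from the mouse cell line CT26 was sequenced in 4 samples, 2 of adherent cells and 2 of passage 1 spheroids. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and libraries were made with an unstranded Illumina kit, so reads from overlapping genes on opposite strands cannot be told apart. Per the series' design text, the authors mapped paired-end reads with STAR (version 2.3.0e), counted them per exon with the script of DEXSeq (version 1.6.0) on UCSC mm9 annotation, and summed the exon counts of each gene with the same package. The deposited values are therefore raw counts per row, with no normalization. Where a read that touches several exons is counted in each, such a sum holds it more than once, and reads without molecular identifiers are not independent molecules, so the floors given cover counting error only. Totals ran from 20160574 to 53510345 counts per library, and a row without counts in a culture was set against a floor of 3 counts over both its libraries, on the scale of the other normalized values and folds. The authors tested them with DESeq2 (version 1.0.19) and selected genes at an adjusted p below 0.1 and an absolute log2 fold change above 1, per the series' design text; their own list of selected genes was not used here.

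The table has 28232 rows. Of these, 16326 hold a single UCSC transcript ID and 11906 join several, up to 47. A joined row can hold the isoforms of one gene or several overlapping genes, and the table does not say which. None of the 55419 transcript IDs matched the gene name tables used here, and no symbol stands in the table. The 37 gene lists set beforehand (pathways, stem cell and surface markers, and markers of other cell types) could therefore not be matched to rows, and no gene set test was run. Markers of other cell types were not examined for the same reason. No coordinates are given. The 4 count columns name the culture by a letter code that the design text explains, but not the replicate number of the labels. They were used as 2 unnumbered libraries per culture and are called shallower and deeper by their totals. No column was left unused.

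Rows were kept where edgeR's filterByExpr found enough counts at its default minimum of 10, which left 12585. Library sizes were scaled by the trimmed mean of M values (TMM), with factors of 0.976 and 0.973 for the adherent and 1.026 for both spheroid libraries. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, default settings) of spheroid against adherent with culture as the only term. Rows were called at a Benjamini-Hochberg adjusted p below 0.1 and an absolute log2 fold change above 1, the thresholds of the design text. The standard error given for a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. Shares of counts use the whole table. Abundance classes use the mean CPM of the 4 libraries.

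The rule for rows named in the text was fixed before the data were examined: called rows with a mean of at least 5 CPM whose libraries do not overlap between cultures, ranked by fold change. It was to name 12 rows in each direction and to leave out predicted genes and rows that join several genes. Since the rows carry no gene names, those exclusions could not be applied and 2 rows in each direction are named. A further part of the rule, the 3 rows with the largest share of all counts, is given by value without IDs. The parts that named members of the gene lists could not be used.

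The noise between 2 libraries was measured per row as the squared deviation from the share given by the totals, divided by its binomial variance, and averaged or taken as a median scaled to the chi-square distribution with 1 degree of freedom. The coefficient of variation beyond sampling noise was taken from rows of 5000 to 20000 counts over the pair, after subtracting the mean ratio of rows of 20 to 100 counts. On simulated pairs with true coefficients of 0, 1, 3 and 10% it gave 0.193, 1.13, 3.07 and 10.1%. The simulated pairs had equal depth. Their mean ratios in rows of 20 to 100 counts were 1.019, 1.007 and 1.002 at coefficients of 0, 1 and 3%, and 1.188 at 10%. The subtraction was therefore not tested at the larger ratios of the real pairs. The edgeR script was tested on counts simulated for the 12585 tested rows, with 200 rows of at least 1 CPM changed. Recovery of changes in rows below 1 CPM was therefore not tested. The simulated spread was the one estimated from these same library pairs, so recovery and false calls at a larger spread between cultures were not tested. All 67 rows changed 3-fold and all 66 changed 8-fold were called in the right direction, none of the 67 changed 1.5-fold passed the fold limit although 62 passed the adjusted p, and 1 of the 12201 unchanged rows whose simulated counts passed the count filter was called.

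Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings, other filters on low counts, other thresholds and each library left out in turn. Alternatives added after seeing the data were the spheroid libraries summed to 1 sample, assumed biological coefficients of variation of 0.1 and 0.4, a test against the fold limit itself (glmTreat), DESeq2 with a prior on fold changes, the newer form of the edgeR fit (legacy = FALSE), a term for a number shared by column names, and rows with 1 transcript ID only.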

Results

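CT26, a mouse colon carcinoma cell line, was profiled by RNA sequencing in 2 culture states. Adherent cells were grown in medium with 20% fetal calf serum. Spheroids at passage 1 were floating clusters collected after 7 days in flasks that prevent attachment, in medium without serum that contained basic fibroblast growth factor and epidermal growth factor at 20 ng/ml each, insulin at 5 µg/ml and 0.4% bovine serum albumin. The series concerns vaccination targets linked to melanoma cancer stem cells, and the comparison asks which transcripts differ between the spheroids and the adherent cells they were derived from. The cultures differed in attachment, serum and supplements together, so the comparison covers all of these at once. Each culture was represented by 2 libraries. Their totals were 29625703 and 53510345 counts for the adherent cells and 20160574 and 20392109 counts for the spheroids. The table holds 28232 rows, each keyed by 1 or more UCSC transcript IDs of the mm9 mouse genome build, of which 9797 had no count in any library. The table pairs no row with a gene symbol, and none of its 55419 transcript IDs matched the name tables used here, so changes are described by row and gene names, functions and positions are not given.

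Spheroids and adherent cells differed across a large part of the transcriptome. Of 12585 rows with enough counts to test, 1518 were higher and 981 were lower in spheroids by more than 2-fold at an adjusted p below 0.1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 2 libraries per culture). These 2499 rows made up 19.9% of those tested, and 60.7% of them were higher in spheroids. The changes reached large sizes in both directions, with rows at 0 in one culture taken at their lower bound. By more than 4-fold, 404 rows rose and 269 fell, and by more than 8-fold 130 rose and 128 fell. By more than 16-fold, 41 rose and 41 fell, and by more than 32-fold 16 rose and 7 fell. At fitted folds without bounds, 19 rose and 20 fell by more than 32-fold. The floor was 0.0721 CPM in spheroids and 0.0371 CPM in adherent cells, which limits measurable falls more than rises. The typical row moved little, with a median absolute fold of 1.37, and 59.9% of tested rows lay within 1.5-fold of equality. The fold limit alone decided the calls, because each of the 2499 rows past 2-fold also passed the adjusted p, the largest being 0.072 in edgeR's test. Without a fold limit 9886 rows, 78.6% of those tested, passed.

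The direction of change depended on abundance. Among the 1203 tested rows with a mean CPM (counts scaled by library size) below 1, 356 were called higher and 209 lower in spheroids, and the median log2 fold change was 0.39 (interquartile range -0.47 to 1.17), a median that was unchanged with the 16 rows at 0 in one culture taken at their lower bound. Among the 2469 rows between 1 and 10 CPM, 521 were called higher and 215 lower, with a median of 0.33 (-0.20 to 0.88). Rows between 10 and 100 CPM, 6530 in number, had 515 calls higher and 345 lower around a median of -0.03, whose sign turned to 0.07 with upper-quartile scaling and to 0.05 with scaling to library size alone. The balance was the opposite among the 2383 rows at 100 CPM or more, where 126 were called higher and 212 lower and the median was -0.21 (-0.57 to 0.19). That median was negative under each of the 3 other scalings as well, between -0.22 and -0.12. The share of rows called is not compared between classes, because the count filter kept the scarcest rows where they passed it in one culture alone.

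The row with the largest rise among those with a mean of at least 5 CPM was the single transcript uc009eml.1, which went from 0.317 ± 0.041 CPM in adherent cells to 42.7 ± 0.400 CPM in spheroids (SD, n = 2 libraries each). Its log2 fold change was 7.09 with a standard error of 0.15 (edgeR adjusted p = 5.839e-24). It was followed by uc008yke.1, which rose from 0.371 ± 0.062 to 27.7 ± 0.305 CPM, a log2 fold change of 6.25 with a standard error of 0.17 (edgeR adjusted p = 8.755e-22). The largest fall among rows with a mean of at least 5 CPM was that of the row uc009bul.1+uc009bum.1+uc009buk.2+uc012ele.1, from 36.1 ± 3.24 to 1.13 ± 0.364 CPM, where the log2 fold change was -5.002 with a standard error of 0.15 (edgeR adjusted p = 1.228e-20). The next was uc008bqy.1+uc008bqv.1+uc008bqu.1+uc008bqw.1+uc008bqx.1, from 46.8 ± 3.26 to 1.52 ± 0.251 CPM, with a log2 fold change of -4.95 and a standard error of 0.13 (edgeR adjusted p = 5.102e-22). The order of these falls reversed without the shallower spheroid library, at log2 fold changes of -4.72 and -5.14. It also reversed in DESeq2 with a prior on fold changes, and held under the other alternatives that tested both rows.

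The 10 most abundant rows held a larger share of the counts in spheroids, while the share of the rows ranked next differed little. The most abundant row of each library took 4.12% ± 0.0061 of spheroid counts and 2.81% ± 0.036 of adherent counts (SD, n = 2 libraries each), and the 10 most abundant rows of each library took 10.2% ± 0.00041 and 6.93% ± 0.0036. The remaining rows among the 100 most abundant took 12.5% ± 0.0035 of spheroid and 12.7% ± 0.012 of adherent counts. The 3 rows with the most counts in the whole table stayed below the 2-fold limit, with log2 fold changes of 0.48, -0.47 and 0.58 (edgeR adjusted p = 3.785e-17, 2.95e-15 and 3.824e-16). At the other end, 31 rows had no count in either spheroid library but at least 20 in the adherent libraries, and 4 rows had none in either adherent library but at least 20 in the spheroids. Set against a floor of 3 counts over the culture without counts, the largest of these differences was at least 23.5-fold lower in spheroids in the former set and at least 20.8-fold higher in the latter. The adherent total was 83136048 counts and the spheroid total 40552683, so the sizes of these sets are not comparable.

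The difference between the cultures far exceeded the difference between libraries of one culture. The median absolute log2 difference was 0.45 between cultures, 0.082 between the adherent libraries and 0.073 between the spheroid libraries. Among all tested rows, 86.5% had both libraries of one culture above both of the other, an arrangement that chance gives in 33.3% of rows with 2 libraries against 2. Within a culture, scarce rows lay closest to sampling noise but above it. The variances in this paragraph are estimated from medians over rows. For rows of 20 to 100 counts, the variance was 1.35 times the Poisson value in the spheroid pair and 1.501 times in the adherent pair. The departure grew as counts rose, more so in the adherent pair. For rows of 5000 to 20000 counts, the variance between the spheroid libraries was 1.94 times the Poisson value and that between the adherent libraries 6.02 times, against 323 times between the shallower library of each culture. Beyond sampling noise, the coefficient of variation was 1.18% between the spheroid libraries and 3.41% between the adherent libraries. The series describes separate experiments. However, the names of the count columns give both libraries of a culture one number in common and a further number that recurs in the other culture, and no label says what these numbers mark. If the pair of a culture is 1 library sequenced again, n is 1 per culture and every p-value here measures technical spread only. The 33.3% would then not apply either, since it takes all libraries as independent. With an assumed biological coefficient of variation of 0.4, 963 of the 2499 rows were still called. That test counted the 2 libraries of a culture as independent, so it does not show what n of 1 per culture would give.

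**Figure D1:**
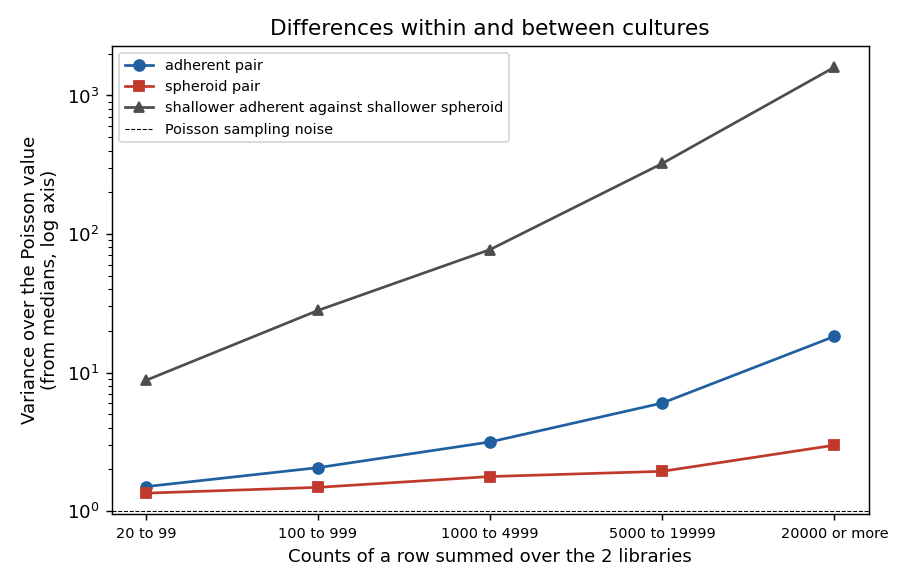
The variance between 2 libraries divided by its Poisson value (log axis, estimated from medians over rows) is plotted against the counts of a row summed over both libraries, for the adherent pair, the spheroid pair and the shallower library of each culture. The spheroid pair runs from 1.35 to 2.99, the adherent pair from 1.501 to 18.2 and the comparison between cultures from 8.78 to 1599, with the dashed line at the Poisson value of 1.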

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

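The alternatives chosen after seeing the data were the assumed coefficients of variation, the test against the fold limit, the prior in DESeq2, legacy = FALSE, the column number term, single-ID rows and the summed spheroid libraries. Across the 21 alternatives, the count of 2499 changed rows stayed within 1.5 times under 17, between 1668 and 3063 rows, and more rows were higher than lower in spheroids under every alternative. DESeq2 called 2374 rows, 2356 of them among the 2499, and DESeq2 with a prior on fold changes called 2206. Leaving out each library in turn gave 2543 to 2669 rows, of which 2285 to 2322 were among the 2499; there, and with the spheroid libraries summed, the lone sample was assumed to vary like the other culture. A filter of 5 CPM in 2 libraries, which drops scarce rows, gave 1524 rows, 944 higher and 580 lower, out of 10004 tested. Of these calls, 1438 were among the 2499. The count of 2499 depends on scarce rows. In the main test, 356 rows were called higher and 209 lower below 1 CPM, and 521 and 215 between 1 and 10 CPM. Dropping the fold limit gave 9886, with 4956 higher and 4930 lower (50.1% higher), near the even split that centring by TMM sets. Rows with a single transcript ID gave 995, with 596 higher and 399 lower, out of 4231 tested. An assumed biological coefficient of variation of 0.4 gave 963, with 609 higher and 354 lower; the same test at 0.1 gave 2500. Testing against the fold limit itself gave 1668 rows, 986 higher and 682 lower, as it requires folds beyond the limit by more than their error. The share higher rose from 60.7% to 68.0% under upper-quartile scaling and 66.8% with library size alone. The 4 named rows kept their direction and their call under every alternative that tested them; the rows joining several IDs were not in the single-ID test. No paired analysis was possible because the columns carry no replicate number from the labels. No label says whether another number that the column names share across cultures pairs the libraries; differences taken by it had a correlation of 0.0053 across rows, and a term for it gave 2503 rows. Leaving out rows that join several genes could not be run as written, since the table does not tell such rows from isoforms of one gene; nor could the gene list tests. The edgeR setting legacy = TRUE was the default; FALSE gave 2500. Depth set a floor of 0.0721 CPM for rows without spheroid counts.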

Other observations

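The test of stray reads, the tests of why libraries of a culture were so close, and the correlation with the difference between cultures were chosen after the values concerned had been seen. The thinning tests and the test without the most different rows were set before their results were seen.

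Scarce rows tended to be higher and abundant rows lower in spheroids, with class medians of 0.39 and -0.21. The values argue against the difference in depth between the cultures as the cause. With all libraries thinned to one total, the gap between the medians of these classes was 0.738, against 0.604 in the data as deposited. The count filter and the classes were set again on the thinned counts, so the rows of a class can differ between these gaps. A background of stray reads in the spheroid libraries was first to be judged by whether both held counts in more rows at equal depth; they did, by 92 rows or more, against ranges of 131 rows within the adherent and 76 within the spheroid pair, so another test was set. To raise the typical row of 1 to 10 CPM by its median, a background spread evenly over rows would need 33.3 counts per row over both spheroid libraries, while among 10583 rows at 0 in both adherent libraries the 90th percentile was 0 counts and 7.43% had any, which argues against an even background and leaves an uneven one open. A broader set of weakly transcribed genes in spheroids stays open as a hypothesis: at equal depth the lower spheroid library had at least 5 counts in 275 more rows than the higher adherent library, against ranges of 30 rows within each pair, though the rise of scarce rows gives such a gap by itself. Differences in RNA quality were not tested.

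The libraries of each culture differed by only a few percent beyond sampling noise, although the series describes separate experiments. Counting a read in several exon bins may explain why even scarce rows exceeded Poisson noise. For rows of 20 to 100 counts the variance, here as a mean over rows, was 1.51 times the Poisson value in the adherent pair. It was 1.41 times in the spheroid pair, a ratio of 0.934. Counting both mates of a read pair or duplicate reads would have the same effect and was not separated from it. Larger spread between libraries in scarce rows was not separated from it either: in simulated pairs a true coefficient of 10% alone gave a ratio of 1.188. Beyond that floor, the coefficient of variation was 3.41% in the adherent pair and 1.18% in the spheroid pair. Repeat sequencing of a single library with sampling noise alone would leave almost no coefficient: simulated pairs at 0% gave 0.193%. The adherent 3.41% argues against that simplest form for the adherent pair. Repeat sequencing with differences between runs cannot be told apart from closely matched independent cultures, since both allow such small values. The column names leave it open too: both libraries of a culture share one number, as lanes of 1 indexed library would.

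The adherent libraries differed more from each other than the spheroid libraries did. Their greater depth is argued against as the cause, because at one total for all libraries the adherent coefficient of variation was still 2.86 times the spheroid one. A few very different rows are argued against as well, since without the 5% most different rows in each pair, among rows of at least 1000 counts, the adherent variance ratio was 2.68 times the spheroid one. A shift of one adherent culture towards the spheroid state as the main source has little room: across 8913 rows at 10 CPM or more, which are not independent replicates, the squared correlation of the adherent difference with the difference between cultures was 0.0097. A difference between separate adherent cultures and a difference between sequencing runs both stay open and were not tested.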
